A study of Mus musculus with 120 samples.

How the data were processed

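Bulk RNA-seq counts were read for 120 libraries of retrogradely labelled mouse thalamic neurons. Per the labels' protocols, cells were picked by hand after labelling from a target region, RNA was extracted with the PicoPure kit with ERCC spike-ins, cDNA was amplified with the Ovation RNA-seq kit, version 2, and libraries were sequenced on an Illumina HiSeq. The kit does not mark the strand, so reads of a gene and its antisense partner cannot be told apart, and genes that share reads with a close copy are uncertain. Per the submitters' processing notes, the tools were cutadapt 1.16, STAR 2.5.3a and featureCounts 1.52 and the genome build was mm10, with settings not given in the sources used here. The authors deposited whole-number counts per gene, without normalization, in a table of 16538 genes, and a second table with the tracer, target, sex, amplification date, animal and number of cells of each library. Every gene in the table had a total of at least 23 counts and reads in at least 3 libraries, so genes with fewer are not analysed here. Of the gene identifiers 16501 matched the mm10 gene annotation without the version suffix and 13921 with it, 13452 symbols were equal, and 5 symbols occurred more than once. Gad1 and Gad2, fixed among the genes to name, are not analysed here.

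Total counts per library ran from 8159497 to 26444831, which were 29.3 to 66.8% of the uniquely mapped reads (median 49.7%), and 10189 to 15504 genes were detected per library. The ribosomal RNA gene Rn18s held 0.0569 to 4.74% of the counts. The libraries were grouped by nucleus, tracer and target from their labels, into 24 groups of 1 to 9. They were made on 14 amplification dates from 85 animals, of which 44 gave more than 1 library, and 13 libraries pooled cells of several animals. By the recorded sex 72 libraries came from males, 47 from females, and 1 was mixed. Cells were amplified without molecular identifiers, so intervals and floors cover counting error only. Of 284 pairs of libraries within groups none had identical counts, and the chi-square of their counts over genes with a summed count of at least 10 was 40.3 to 489.8 times its degrees of freedom, so each library was counted as 1 sample.

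Counts were tested with edgeR 4.0.16 in R 4.3.3. A single fit held all libraries with 1 coefficient per group, TMM factors, filterByExpr on the groups (minimum count 10, minimum total count 15, which left 16527 genes), estimated dispersions and the quasi-likelihood F test. A call is a Benjamini-Hochberg adjusted p under 0.05, and all tests are two-sided. CM was taken from its AAV libraries and AM from its DiI libraries wherever 22 nuclei were compared. The 11 pairwise comparisons were contrasts of this fit between groups labelled from the same target. PF and PVT were set against the mean of 3 intralaminar groups, and each nucleus against the mean of the other 21. For striatum-labelled against cortex-labelled nuclei the counts of each nucleus were summed and the 7 sums tested against the 15 in a fit of their own. Values in the text are CPM, computed here from the deposited counts with TMM-scaled library sizes, as mean ± SD over libraries, or over nuclei for that comparison.

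A fold against a group with no read is a lower bound from a floor of 3 counts over the summed library size of the group, and with 1 to 3 counts the ratio has a 95% counting interval. Principal components used the nucleus means of log2 CPM (prior count 2) over the 500 genes with the largest F. The 27 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated, where at least 2 members were measured, with adjustment over the lists of a comparison. Agreement between comparisons is Pearson's r of log2 fold changes across genes, with an exact relabelling of the libraries of one comparison. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

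The groups, comparisons, gene lists, rule for named genes and a first set of alternative settings were chosen before the data were examined. In the first 5 pairwise comparisons the rule takes the 8 largest changes in each direction among called genes with a mean of at least 10 CPM in the higher group and ranges that do not overlap. In the other 6 it takes the 3 largest, and for striatum against cortex the 8 largest without the condition on ranges. It adds up to 2 members per direction from each list, the 20 genes with the largest F, 1 marker per nucleus and 11 fixed genes, and leaves out Gm and Rik models. Some genes it picks are not used here. The genes named as shared by the LP, PO and VM comparisons and those named for principal component 1 were picked after their values were seen.

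These settings were RLE size factors, DESeq2 1.42.0, no filter on low counts, a fit of the compared groups alone, the replicate number as a block, leaving out each library in turn, and other gene choices for the components. Chosen after the data were seen were edgeR's newer quasi-likelihood fit (legacy=FALSE), a stricter filter (at least 10 CPM in at least 3 libraries), limma-voom with the animal as a random block, fits within shared amplification dates, fits of animals that gave both sides, and fits without 6 doubted libraries. Of those 6, 3 had oligodendrocyte markers that summed to over 1000 CPM and 3 had Xist over 100 CPM although recorded as male. Refits of subsets reused the dispersion trend of the fit of all libraries.

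Replicate numbers were checked for pairing before fits were compared. For RE and AM, 4 of 4 shared numbers came from the same animal, so these numbers pair the samples, although deviations from the group means of same-numbered libraries correlated at a mean of -0.00598. For VM and VL 3 of 6, for AD and AV 2 of 4 and for VA and VL 1 of 6 came from the same animal, and in the other comparisons none did. No same-numbered pair of libraries correlated above 0.1. Since many animals gave several libraries, p-values that take libraries as independent are approximate.

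The tests were run on simulated counts with 200 changed genes. Of genes changed 4-fold and 16-fold the fit recovered 66 and 97% for LP against LGd, 51 and 93% for PO against VB, 63 and 93% for PF and 32 and 83% for IAD against AM, with 8, 5, 20 and 4 false calls among 16527 genes. For striatum against cortex it recovered 90 and 99%, with 33 false calls among 16024 genes. With no gene changed VM against VL had 0 calls, but its real libraries regrouped at random up to 78, so no error rate follows.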

Results

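Projection neurons of 22 nuclei of the mouse thalamus were labelled from the region they project to, dissected, collected by hand as small pools and sequenced as bulk RNA. The tracer was DiI, a lipophilic dye taken up by axon endings, in 92 libraries and an AAV, a viral vector carried back from axon endings, in 28. The striatum was the target for 7 nuclei, namely PVT (paraventricular), IMD (intermediodorsal), PCN (paracentral), CM (central medial), CL (central lateral), PF (parafascicular) and SPA (subparafascicular area). The other 15 were labelled from the cortex. LP (lateral posterior) and LGd (dorsal lateral geniculate) were labelled from primary visual cortex, PO (posterior) and VB (ventrobasal) from barrel cortex, and VM (ventromedial), VL (ventrolateral) and VA (ventral anterior) from primary motor cortex. AD (anterodorsal), AV (anteroventral) and LD (laterodorsal) were labelled from retrosplenial cortex, AM (anteromedial), RE (reuniens) and IAD (interanterodorsal) from cingulate cortex, VPMpc (parvicellular ventral posteromedial) from insular cortex and MD (mediodorsal) from orbital cortex. CM and AM were labelled with both tracers. A library held 14 to 200 cells (median 60.5), and the median total count was 15571299.5. The comparisons address how the transcriptomes of thalamic projection neurons differ between nuclei, and between nuclei that share a target. Values below are counts-per-million (CPM), mean ± SD over libraries, and adjusted p-values are Benjamini-Hochberg from edgeR's quasi-likelihood test, unless named otherwise.

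All 22 nuclei expressed the vesicular glutamate transporter Slc17a6 and Tcf7l2, a transcription factor of the developing thalamus. No library fell below 518 CPM for Slc17a6 or 813 CPM for Tcf7l2. Slc17a6 ran from 717 ± 115 CPM (n = 8) in RE to 1635 ± 239 CPM (n = 4) in SPA, and Tcf7l2 from 1024 ± 79.2 CPM (n = 3) in PVT to 2866 ± 929 CPM (n = 6) in MD. The cortical vesicular glutamate transporter Slc17a7 spanned a far wider range, from 1.25 ± 1.77 CPM (n = 4) in SPA to 518 ± 222 CPM (n = 4) in AD. Calcium-binding proteins also parted the nuclei. Calb2, calretinin, reached 745 ± 190.3 CPM (n = 3) in PVT and 0.0590 ± 0.0649 CPM (n = 6) in VL, and Calb1, calbindin, 542 ± 211 CPM (n = 8) in VA and 1.37 ± 2.63 CPM (n = 4) in AD. Parvalbumin, Pvalb, stood at 76.4 ± 32.4 CPM (n = 6) in VL and was not counted in the 3 PVT libraries. Necab1 ranged from 5.51 ± 7.52 CPM (n = 8) in AV to 2368 ± 861 CPM (n = 6) in MD. Tnnt1, a troponin, ranged from 0.128 ± 0.112 CPM (n = 3) in PVT to 239.6 ± 58.4 CPM (n = 5) in LGd. The homeobox factor Gbx2 ranged from 1.601 ± 1.46 CPM (n = 5) in LD to 209.8 ± 37.8 CPM (n = 4) in IMD. The test that the 22 nuclei have equal means called 9113 of 16527 genes, against a median of 2480 when libraries were regrouped at random. Its largest F belonged to Slc24a2, a potassium-dependent sodium-calcium exchanger, which stood at 6422 ± 2227 CPM (n = 4) in VB and 158 ± 57.9 CPM (n = 4) in SPA. Rasgrp1, an activator of Ras near the top of that ranking, stood at 2936 ± 249.7 CPM (n = 5) in LGd and 254 ± 45.8 CPM (n = 4) in SPA. Rgs4, a regulator of G protein signalling, stood at 1132 ± 265 CPM (n = 6) in VM and 59.4 ± 35.2 CPM (n = 4) in CM. The NMDA receptor subunit Grin2b stood at 7542 ± 1649 CPM (n = 6) in MD against 872 ± 136 CPM (n = 3) in PVT. Complexin 1, Cplx1, which acts at synaptic vesicle fusion, stood at 1374 ± 270.3 CPM (n = 6) in VL against 30.4 ± 11.6 CPM (n = 4) in SPA. The libraries came from 85 animals and were amplified on 14 dates.

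Nuclei labelled from the striatum differed from nuclei labelled from the cortex in 2837 of 15440 genes when counts were summed per nucleus and the 7 were compared with the 15. The striatum-labelled nuclei were higher in 1324 genes and lower in 1513. In this fit the 7 nuclei were labelled by AAV and the 15 by DiI, so tracer and class coincide, and with CM from its DiI libraries 2519 genes were called. Sex partly followed class and was not modelled: PVT, IMD, CL, PF and SPA were female only, and AD, AV, LD, LGd, LP, MD, PO and VB male only. AM, labelled from the cortex, was female only as well. On the 2 of 14 amplification dates that held both classes, counts summed per nucleus and date (PVT, IMD and CM against VM and, on both dates, VA and VL, all 3 labelled from M1, date as a block) called 874 of 14677 genes, 365 higher and 509 lower. Among the genes named here, Clic5, Hrh3, Fos, Atp2b4, Adgrg6, Efhd1 and Ndufv3 lost their call within these dates, and Ndufa2 turned to -0.0506 on the log2 scale. Over nuclei, they were higher in Npy2r, a neuropeptide Y receptor (43.0 ± 31.5 against 0.104 ± 0.330 CPM, edgeR adjusted p = 1.91e-05). The neurokinin B receptor Tacr3 (32.8 ± 23.6 against 0.192 ± 0.436 CPM, edgeR adjusted p = 0.000171) and the galanin receptor Galr1 (35.7 ± 23.5 against 0.955 ± 2.16 CPM) were higher as well. Large increases were also seen in the vesicular zinc transporter Slc30a3 (37.2 ± 38.3 against 0.313 ± 0.833 CPM) and the receptor tyrosine kinase-like Ror1 (12.1 ± 9.12 against 0.0943 ± 0.177 CPM). Rgs10 (24.0 ± 17.1 against 0.559 ± 0.645 CPM) and Clic5 (21.2 ± 14.98 against 0.512 ± 0.838 CPM) rose too. The peptide galanin itself, Gal, was higher too (26.4 ± 17.1 against 1.25 ± 2.14 CPM), as was the cannabinoid receptor Cnr1 (128 ± 50.3 against 5.30 ± 7.003 CPM). So were the histamine receptor Hrh3 (213 ± 25.4 against 110.4 ± 34.2 CPM) and the immediate early gene Fos (43.4 ± 14.2 against 11.8 ± 7.14 CPM). Among channels and synaptic proteins, the T-type calcium channel Cacna1i (59.1 ± 15.3 against 4.48 ± 6.73 CPM) and the potassium channel interacting protein Kcnip1 (50.2 ± 22.2 against 2.48 ± 4.90 CPM) were higher. The metabotropic glutamate receptor Grm8 (68.5 ± 14.2 against 4.80 ± 8.69 CPM) and synapsin 2, Syn2 (1393 ± 117 against 222 ± 173 CPM), were higher too. Gbx2 rose from 27.6 ± 19.3 CPM in the cortex-labelled nuclei to 132.5 ± 56.5 in the striatum-labelled ones, and Slc17a6 from 1108 ± 234.6 to 1567 ± 75.2.

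The cortex-labelled nuclei were higher in Slc17a7, which stood at 4.54 ± 2.38 CPM in the striatum-labelled nuclei (SD, n = 7) against 208 ± 176 in the cortex-labelled nuclei (n = 15) (edgeR adjusted p = 0.000115). They were also higher in the transcription factor Sox5 (0.944 ± 1.06 against 98.7 ± 65.1 CPM, striatum-labelled value first here and below). The extracellular matrix protein Fras1 (2.17 ± 3.09 against 222 ± 97.2 CPM) and Hs3st4, a heparan sulfate sulfotransferase (0.0283 ± 0.0526 against 18.2 ± 25.7 CPM), were higher in them too. The plasma membrane calcium pump Atp2b4 (0.0584 ± 0.0920 against 32.2 ± 49.5 CPM), the adhesion receptor Adgrg6 (0.182 ± 0.355 against 36.0 ± 43.7 CPM) and Efhd1 (0.0727 ± 0.145 against 12.4 ± 9.69 CPM) followed the same direction. Of 33 measured voltage-gated potassium channel genes, 1 was higher and 13 lower (2 and 15 with p adjusted over the list alone). Kcnc2 stood at 414 ± 142 against 1018 ± 223 CPM. Of 12 sodium channel genes, 0 were higher and 4 lower (1 and 4 adjusted over the list alone), among them Scn8a (407 ± 111 against 1108 ± 349 CPM) and Scn1a (334 ± 166 against 791 ± 309.8 CPM), and the list did not differ from other genes (camera adjusted p = 0.331, and adjusted p = 0.502 with an estimated correlation). Of 56 adhesion genes, 3 were higher and 17 lower (3 and 18 over the list alone). Lrrtm2 stood at 176 ± 47.4 against 736 ± 294 CPM. The potassium channel and adhesion lists did not differ from other genes (camera adjusted p = 0.0608 and 0.0972, and 0.444 and 0.594 with an estimated correlation). Of 81 oxidative phosphorylation genes, 27 were higher and 1 lower (41 and 2 over the list alone) in the striatum-labelled nuclei. Ndufv3 stood at 75.0 ± 20.9 against 34.7 ± 16.3 CPM and Ndufa2 at 69.4 ± 34.3 against 25.6 ± 16.8 CPM. The list test called that list higher only with the preset correlation (camera adjusted p = 4.64e-10, and 0.566 with an estimated correlation). Of 12 measured oligodendrocyte markers, 0 were higher and 7 lower (0 and 7 over the list alone). The myelin gene Mobp (0.119 ± 0.161 against 13.99 ± 23.1 CPM) was lower. This list too lost its call with an estimated correlation (camera adjusted p = 0.00146, and 0.444 with an estimated correlation).

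Igkc, the constant region of the immunoglobulin kappa light chain (mm10 chromosome 6, 70726435 to 70726966, ENSMUSG00000076609.2), separated the classes without overlap. It stood at 33.8 ± 17.4 CPM over the 30 striatum-labelled libraries, with a range of 8.30 to 69.6 CPM. Of the 90 cortex-labelled libraries 88 had no Igkc read, and the highest had 0.0539 CPM. The single AM library labelled by AAV from the cortex had none, while the 3 CM libraries labelled by DiI from the striatum lay between 8.30 and 30.5 CPM. On the 2 amplification dates that held both classes, the lowest of 10 striatum-labelled libraries stood at 8.30 CPM and the highest of 16 cortex-labelled libraries at 0.0517 CPM. None of the nuclei was labelled from both the striatum and the cortex, so target and nucleus cannot be told apart here. In the annotation Igkc lies inside the span of a non-coding gene, Gm30211 (chromosome 6, 70719074 to 70740554, same strand), whose exons do not overlap it. The counting settings are not stated, so reads from another transcript of this locus are not excluded. The joining segment Igkj1 was counted in 28 of the 30 striatum-labelled and 0 of the 90 cortex-labelled libraries.

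**Figure D1:**
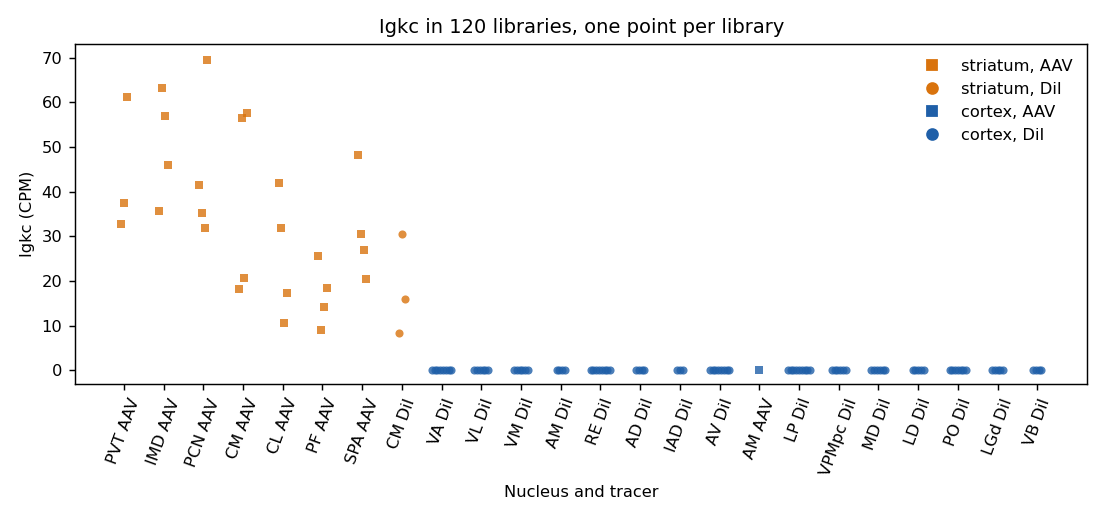
Igkc in every library, in CPM, by thalamic nucleus and tracer, with squares for AAV and circles for DiI, orange for libraries labelled from the striatum and blue for libraries labelled from the cortex. The 30 striatum-labelled libraries lie between 8.30 and 69.6 CPM and the 90 cortex-labelled ones at or below 0.0539 CPM.

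The first principal component of the nucleus means, over the 500 genes with the largest F, held 49.8% of the variance and placed the 7 striatum-labelled nuclei below the other 15. PVT (-48.0), IMD (-45.4) and SPA (-43.9) lay at one end and VB (44.8), LGd (44.5) and LD (33.2) at the other. PCN (-25.3) was the highest striatum-labelled nucleus and RE (-14.6) the lowest cortex-labelled one, followed by AM (-5.45) and IAD (-0.884). Genes that weighed most on the striatal end included Fbln1, Cnr1, Lypd6, Grm8 and Galr1, and on the cortical end Fras1, Sox5, Car4, Slc17a7, Esrrg and Prkcd. Xist, the RNA of the inactive X chromosome, weighed most on the striatal end, and without Xist, Tsix and Y-linked genes the component held 49.7% and gave the nuclei the same order (Spearman rho = 1). The single AAV-labelled AM library scored 3.59, above its 4 DiI-labelled counterparts (-9.77 to -1.81), and the 3 DiI-labelled CM libraries scored -22.97 or less. Within the 16 nuclei labelled by DiI alone the component held 31.8% and ordered the 15 cortex-labelled nuclei much as before (Spearman rho = 0.914), and CM (-21.6) no longer lay beyond the lowest cortex-labelled nucleus (-38.9). Single libraries of the classes overlapped slightly, with the highest striatum-labelled library at -18.6 and the lowest cortex-labelled one at -19.1. On the 2 dates that held both classes every striatum-labelled library lay below every cortex-labelled one, by at least 33.8 and 57.9.

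**Figure D2:**
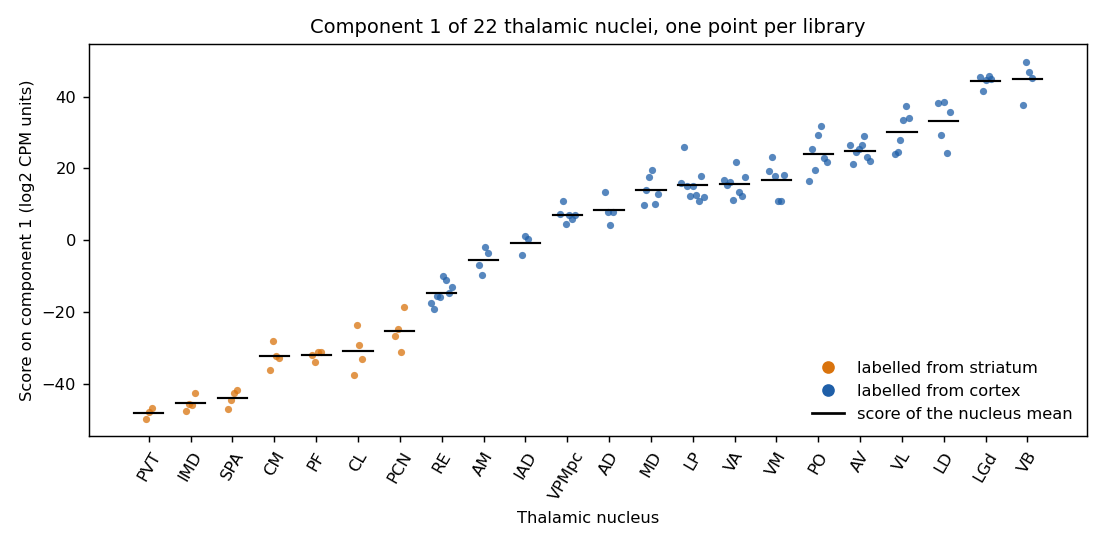
Score of each library on principal component 1 (log2 CPM units) by thalamic nucleus, ordered by the score of the nucleus mean (black bars), with orange points for nuclei labelled from the striatum and blue points for nuclei labelled from the cortex. The 7 striatum-labelled nuclei lie at -25.3 or less and the 15 cortex-labelled nuclei at -14.6 or more.

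LP and LGd, a higher-order and a first-order visual nucleus labelled from the same cortex, differed in 599 of 16527 genes, of which 369 were higher in LP and 230 higher in LGd. The voltage-gated calcium channel Cacna1e stood at 312 ± 93.4 CPM in LP (SD, n = 9) against 5.67 ± 11.3 in LGd (n = 5) (edgeR adjusted p = 2.22e-08). The plasma membrane calcium pump Atp2b4 (mm10 chromosome 1, 133699457 to 133801041, ENSMUSG00000026463.17) stood at 121 ± 34.7 against 0.0324 ± 0.0726 CPM, 3728-fold (counting interval 1034 to 30831). The inward rectifier potassium channel Kcnj2 (22.1 ± 13.9 against 0 CPM) and the vesicle protein Syt10 (15.95 ± 9.17 against 0 CPM) had no read in any LGd library and were at least 454-fold and at least 328-fold higher in LP. LGd was higher in Scnn1a, a subunit of the epithelial sodium channel (0.0229 ± 0.0688 against 40.1 ± 8.64 CPM, LP first), and in Gcnt4, a glycosyltransferase (0 against 23.4 ± 9.64 CPM, at least 933-fold lower in LP). Parvalbumin, Pvalb, was lower in LP (0.0901 ± 0.204 against 26.1 ± 8.88 CPM), as was the fast voltage-gated potassium channel Kcnc1 (364 ± 114 against 819.6 ± 156 CPM).

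Of 12 voltage-gated sodium channel genes, 2 were higher and 4 lower (4 and 4 over the list alone) in LP. Scn2a (684 ± 89.9 against 322 ± 65.9 CPM) and Scn3b (177 ± 55.9 against 24.1 ± 14.9 CPM) were higher, and Scn1a (620.1 ± 126 against 1144 ± 99.2 CPM) and Scn4b (4.25 ± 4.41 against 97.0 ± 37.5 CPM) lower. Of 20 GABA and glycine receptor genes, 8 were higher and 4 lower (8 and 6 over the list alone). The list as a whole lay higher in LP (camera adjusted p = 0.000855, and 0.0125 with an estimated correlation). Gabra3 (171 ± 62.3 against 2.69 ± 3.33 CPM) and Gabrg1 (47.4 ± 28.2 against 0.0656 ± 0.106 CPM) rose, and Gabrb2 (461 ± 71.1 against 774 ± 96.1 CPM) fell. Of 56 adhesion genes, 11 were higher and 3 lower (12 and 3 over the list alone). Against all other genes the list lay higher in LP (camera adjusted p = 7.14e-05, and 0.0125 with an estimated correlation). The protocadherins Pcdh17 (105 ± 67.4 against 1.34 ± 1.73 CPM) and Pcdh19 (234 ± 83.4 against 36.7 ± 10.96 CPM) rose and Cdh4 fell (3.25 ± 2.94 against 40.1 ± 23.1 CPM). Of 18 neuropeptide list members, 2 were higher and 0 lower (3 and 0 over the list alone). Set against other genes, these lay higher in LP (camera adjusted p = 7.14e-05, and 0.00704 with an estimated correlation). The 2 that rose, Nxph1 (113 ± 45.4 against 0.481 ± 0.454 CPM) and Cbln4 (12.4 ± 10.2 against 0.633 ± 0.966 CPM), are secreted synaptic organisers. Among the 3 measured astrocyte list members the glutamate transporter Slc1a2 rose (1254 ± 288 against 413 ± 81.5 CPM). Camera placed the list higher in LP (camera adjusted p = 0.00208, and 0.00704 with an estimated correlation). Of 24 glutamate receptor genes, 5 were higher and 1 lower (6 and 3 over the list alone). Grin3a stood at 138 ± 57.7 against 3.18 ± 4.33 CPM and Grm5 at 399.6 ± 111 against 147 ± 12.95 CPM. This list kept its call only with the preset correlation (camera adjusted p = 0.0193, and 0.0599 with an estimated correlation).

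Of 81 oxidative phosphorylation genes, 0 were higher and 3 lower (1 and 10 over the list alone) in LP, a call that also needed the preset correlation (camera adjusted p = 5.09e-08, and 0.0652 with an estimated correlation). Serotonin receptor Htr2c (170.1 ± 57.9 against 1.76 ± 3.04 CPM) and the opioid receptor Oprm1 (47.3 ± 31.8 against 0.308 ± 0.430 CPM) were higher in LP. So were the calcium-binding proteins Necab1 (1556 ± 526 against 115 ± 68.4 CPM) and Hpcal4 (109 ± 49.4 against 4.64 ± 2.44 CPM), as well as Calb1 (173 ± 40.1 against 39.7 ± 5.15 CPM) and Calb2 (115 ± 65.8 against 5.65 ± 8.75 CPM). Semaphorin Sema5a (300.1 ± 108 against 1069.7 ± 212 CPM) and the neurofilament subunit Nefm (252 ± 107 against 789.6 ± 140.2 CPM) were higher in LGd. The vesicle proteins Vamp1 (89.3 ± 31.2 against 415 ± 34.1 CPM) and Cplx1 (382 ± 122 against 1122 ± 97.5 CPM) were higher in LGd as well. Within the 1 date that held both nuclei (7 libraries against 5) the count was 537. DESeq2 called 1146 genes, 74.4% of them higher in LP against 61.6% with edgeR. The summed oligodendrocyte markers reached 1102 CPM in LP replicate 1.

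PO and VB, a higher-order and a first-order somatosensory nucleus, differed in 438 genes, with 265 higher in PO (n = 7) and 173 higher in VB (n = 4). PO was higher in Cacna1e (181 ± 62.8 against 0.135 ± 0.117 CPM, edgeR adjusted p = 1.21e-10) and in Calb2 (56.8 ± 36.5 against 0.114 ± 0.0926 CPM). Among genes without a read in VB were Defb1, a defensin (28.4 ± 17.6 against 0 CPM, at least 464-fold), and the glycine receptor subunit Glra3 (23.8 ± 10.9 against 0 CPM, at least 388-fold). The GABA receptor subunit Gabrg1 (14.7 ± 10.8 against 0 CPM, at least 239.5-fold) and the synaptic organiser Cbln4 (12.8 ± 14.5 against 0 CPM, at least 209-fold) had none there either. VB was higher in Gcnt4 (0.0392 ± 0.0548 against 34.0 ± 15.3 CPM), Stac2 (0.04998 ± 0.0529 against 27.6 ± 23.0 CPM) and Pvalb (0.114 ± 0.0865 against 53.7 ± 17.9 CPM). Fam19a1 was higher there as well (0.0106 ± 0.0281 against 17.4 ± 7.89 CPM, 1640.0-fold (counting interval 322 to 70851)).

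Of 14 neurofilament and axon caliber genes, 3 were higher and 7 lower (3 and 9 over the list alone) in PO. Tested as a set, the members lay lower in PO (camera adjusted p = 0.000686, and 0.0272 with an estimated correlation). Nefh (111 ± 30.3 against 555 ± 142 CPM) and Nefm (318 ± 138 against 1176 ± 582 CPM) fell and the growth cone protein Gap43 rose (403 ± 47.5 against 165 ± 85.9 CPM). Of 24 glutamate receptor genes, 4 were higher and 2 lower (7 and 2 over the list alone). The list lay higher in PO (camera adjusted p = 0.000508, and 0.0169 with an estimated correlation). Grin3a (125 ± 22.7 against 12.4 ± 22.2 CPM) and Grm5 (346 ± 91.5 against 126 ± 46.5 CPM) rose and Grin2a fell (428 ± 50.1 against 1080.3 ± 379 CPM). Among 56 adhesion genes, 7 were higher and 3 lower (12 and 3 over the list alone). The list as a whole lay higher in PO (camera adjusted p = 0.000508, and 0.0414 with an estimated correlation). Lrrtm4 stood at 50.1 ± 34.0 against 0.878 ± 0.890 CPM and Pcdh7 at 143 ± 37.9 against 457 ± 207 CPM. Of 48 axon guidance genes, 6 were higher and 5 lower (13 and 7 over the list alone). Against all other genes the list lay higher in PO (camera adjusted p = 0.0162, and 0.0470 with an estimated correlation). Plxnc1 stood at 353 ± 59.8 against 33.2 ± 20.5 CPM and Sema6d at 61.3 ± 28.0 against 553 ± 126 CPM. Of 26 monoamine and related receptor genes, 5 were higher and 1 lower (7 and 2 over the list alone), and Htr2c was 1 of the higher ones (89.7 ± 55.4 against 3.38 ± 3.81 CPM). Of 81 oxidative phosphorylation genes, 0 were higher and 1 lower (0 and 1 over the list alone). Of 12 oligodendrocyte markers, 0 were higher and 0 lower (0 and 1 over the list alone). The monoamine receptor list lay higher and both these lists lower in PO (camera adjusted p = 0.0150, 1.85e-08 and 8.08e-05, and 0.0470, 0.0470 and 0.104 with an estimated correlation). With the correlation estimated, 7 lists were called. Oligodendrocyte markers summed to 859.0 ± 958.7 CPM in VB and 110.6 ± 98.6 in PO, with 2212 CPM in VB replicate 4. Inhibitory neuron markers summed to 64.2 ± 23.6 in VB and 7.40 ± 9.90 in PO, and astrocyte markers to 488 ± 251 and 930 ± 181.

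Sodium channel subunits Scn2a (604 ± 65.4 against 234 ± 60.3 CPM) and Scn3b (123 ± 40.01 against 4.06 ± 5.79 CPM) were higher in PO. Transcription factors Foxp1 (156 ± 49.8 against 35.6 ± 14.4 CPM) and Foxp2 (554 ± 118 against 110.0 ± 85.7 CPM) and the vesicle protein Syt16 (46.0 ± 19.3 against 1.67 ± 2.46 CPM) rose as well. The nuclear receptor Rorb (380.2 ± 104 against 1360.2 ± 715 CPM) was higher in VB. Vamp1 (92.6 ± 28.4 against 484 ± 43.8 CPM) and Cplx1 (454 ± 113 against 1133 ± 221 CPM) were higher too. Within the 1 date that held both nuclei (3 libraries against 4) the count fell to 205. DESeq2 called 1214 genes, 73.4% of them higher in PO against 60.5% with edgeR.

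VM and VL, motor nuclei labelled from the same cortex, differed in 280 genes, with 201 higher in VM and 79 higher in VL (6 libraries each). VM was higher in Adgrg6 (17.8 ± 8.86 against 0.0113 ± 0.0277 CPM, 1578-fold (counting interval 339.7 to 74768)), Cacna1e (126 ± 118 against 1.1602 ± 1.17 CPM, edgeR adjusted p = 1.91e-10) and complexin 2, Cplx2 (30.5 ± 36.4 against 0.233 ± 0.126 CPM). It was also higher in the neurotrophin receptor Ntrk3 (50.4 ± 35.6 against 0.851 ± 1.36 CPM), Tmie, a part of the hair cell transduction channel (33.5 ± 14.4 against 0.282 ± 0.447 CPM), and Tmem132d (15.2 ± 19.0 against 0.0607 ± 0.0783 CPM). VL was higher in the thyroid hormone deiodinase Dio2 (0.208 ± 0.307 against 39.4 ± 39.8 CPM) and the muscle-type cytochrome oxidase subunit Cox6a2 (1.78 ± 3.19 against 42.6 ± 32.6 CPM). Rorb (139.6 ± 53.0 against 1144 ± 159 CPM), Pcdh9 (246 ± 32.6 against 997 ± 148 CPM) and Pvalb (3.33 ± 3.31 against 76.4 ± 32.4 CPM) were higher in VL too. The Pvalb call was lost within shared dates, without the doubted libraries and in 6 of the fits that left out 1 library.

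Of 20 GABA and glycine receptor genes, 5 were higher and 0 lower (7 and 0 over the list alone) in VM. Relative to the remaining genes the list lay higher in VM (camera adjusted p = 1.47e-06, and 0.000416 with an estimated correlation). Glra3 was 1 of the higher ones (10.0 ± 14.7 against 0.0776 ± 0.163 CPM). Of 56 adhesion genes, 10 were higher and 2 lower (11 and 2 over the list alone). The list as a whole lay higher in VM (camera adjusted p = 3.05e-08, and 0.000416 with an estimated correlation). Tenm1 (912 ± 219 against 377 ± 39.97 CPM) and Cdh8 (179 ± 41.9 against 48.8 ± 18.5 CPM) rose. Of 14 neurofilament and axon caliber genes, 2 were higher and 4 lower (2 and 6 over the list alone). Against all other genes the list lay lower in VM (camera adjusted p = 0.00213, and 0.0289 with an estimated correlation). Nefm stood at 598 ± 183 against 1636 ± 266 CPM. Of 81 oxidative phosphorylation genes, 0 were higher and 3 lower (0 and 3 over the list alone). Of 4 inhibitory neuron markers, 0 were higher and 1, Pvalb, lower (0 and 1 over the list alone). Both lists lay lower in VM (camera adjusted p = 7.41e-12 and 3.60e-07, and 0.0224 and 0.000380 with an estimated correlation). The inhibitory markers summed to 5.13 ± 4.99 against 89.3 ± 33.0 CPM, and Pvalb, whose call was not stable, made 76.4 CPM of the VL sum. Astrocyte markers summed to 3184 ± 781 against 1994 ± 283 CPM and oligodendrocyte markers to 242 ± 273 against 102.2 ± 87.2, with neither list called (camera adjusted p = 0.895 and 0.191). The calls of Slc1a2 and Aldoc among the 3 astrocyte markers, 1 higher and 1 lower, were lost within the shared date. Of 48 axon guidance genes, 6 were higher and 2 lower (13 and 4 over the list alone). Tested as a set, the members lay higher in VM (camera adjusted p = 0.0253, and 0.0647 with an estimated correlation). Scn2a (656 ± 163 against 307 ± 41.3 CPM), Scn3b (103 ± 67.2 against 4.21 ± 3.80 CPM) and Necab1 (711 ± 261 against 100.5 ± 54.4 CPM) were higher in VM. The count fell to 163 within the 1 shared date (4 libraries each), and to 158 without VM replicate 4 and VL replicate 4, whose sex genes went against their record. It was 115 among animals that gave both nuclei with the animal as a block. It rose to 681 with DESeq2, to 522 with the newer quasi-likelihood fit and to 492 with limma-voom.

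**Figure D3:**
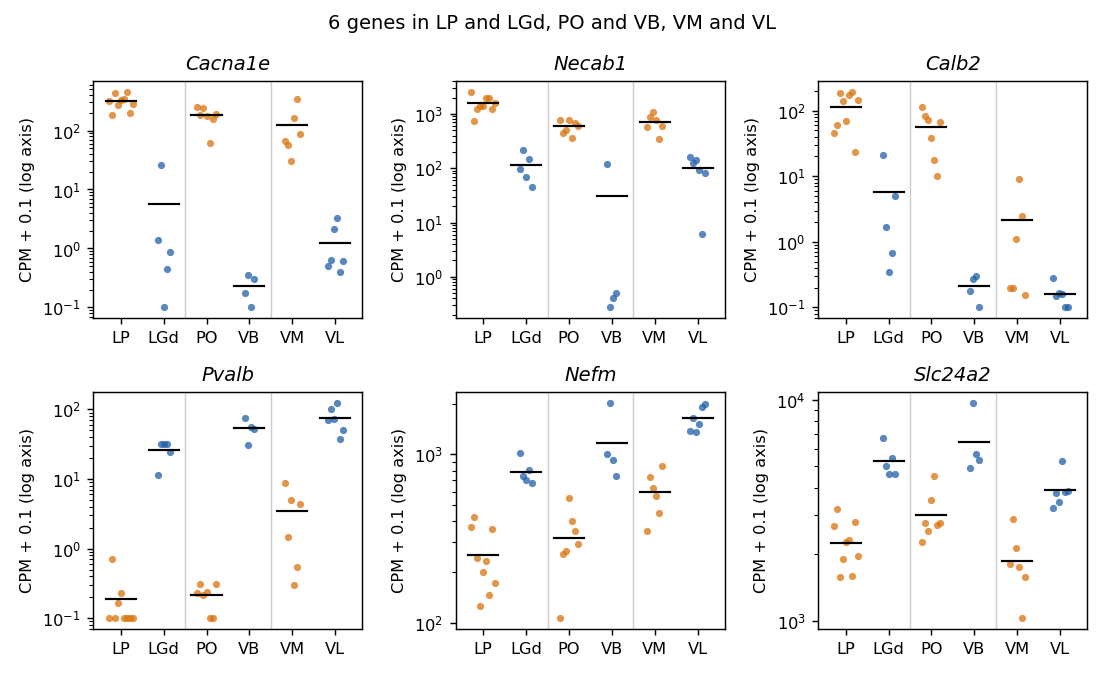
CPM + 0.1 of Cacna1e, Necab1, Calb2, Pvalb, Nefm and Slc24a2 in single libraries of LP, LGd, PO, VB, VM and VL, on a log axis, with orange points for LP, PO and VM, blue points for LGd, VB and VL, and black bars at the means. Mean Cacna1e was 312, 181 and 126 CPM in LP, PO and VM against 5.67, 0.135 and 1.1602 CPM in LGd, VB and VL.

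The changes from LGd to LP, from VB to PO and from VL to VM shared genes well beyond the number that independent lists would give. The LP and PO comparisons called 153 genes higher in common (5.92 expected) and 64 lower (2.41 expected). LP and VM had 115 higher (4.49 expected) and 35 lower (1.10 expected), and PO and VM 97 higher (3.22 expected) and 27 lower (0.827 expected). All 3 comparisons called 76 genes higher (0.0720 expected) and 21 lower (0.0115 expected). The 76 included the channel genes Cacna1e, Scn2a and Scn3b, the receptor genes Glra3, Gabrg1 and Grm5, the calcium-binding Necab1, Calb1 and Calb2, and Plxnc1, Tenm1, Pcdh19, Ncam1, Chl1 and Ntrk3. The 21 included Slc24a2, Kcnc1, Pvalb, Nefh, Nefm, Cplx1, Vamp1 and Ppargc1a, a coactivator of mitochondrial gene expression. The VM calls of Calb1, Calb2 and Pvalb behind these sets were lost without the doubted libraries and without single libraries. Lost too were those of Grm5 and Pvalb within the shared date, Gabrg1 and Calb2 with the newer quasi-likelihood fit, Calb2 with limma-voom and Gabrg1, like the PO call of Necab1, in a fit of the compared groups alone. Across genes, the log2 fold changes of LP and PO correlated at r = 0.242, of LP and VM at 0.163 and of PO and VM at 0.157. Exact relabelling of the libraries of one comparison gave p = 0.0004995, 0.0004995 and 0.00303, the smallest values that the 2002, 2002 and 330 relabellings allow. Over the 8683 genes with a mean of at least 10 CPM, r rose to 0.549, 0.467 and 0.437, while genes are not independent replicates. With DESeq2 fold changes r was 0.236, 0.0717 and 0.0874.

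AD and AV, neighbouring anterior nuclei labelled from retrosplenial cortex, differed in 940 genes, with 461 higher in AD (n = 4) and 479 higher in AV (n = 8). AD was higher in the orphan receptor Gpr139 (239.6 ± 54.6 against 0.0262 ± 0.0496 CPM, edgeR adjusted p = 6.33e-07) and the muscarinic receptor Chrm1 (117 ± 69.6 against 0.0310 ± 0.0877 CPM). Higher levels also marked the serotonin receptor Htr2a (31.0 ± 22.5 against 0 CPM, at least 1064-fold). It was also higher in Slc17a7 (518 ± 222 against 8.11 ± 9.81 CPM) and the synaptic organiser Nxph1 (507 ± 54.6 against 75.2 ± 37.2 CPM). The same held for the calcium-binding S100a10 (19.1 ± 13.5 against 0.0155 ± 0.0438 CPM) and Gabra2 (303 ± 190.5 against 12.8 ± 24.1 CPM). AV was higher in the neuropeptide S receptor Npsr1 (0.0207 ± 0.0414 against 189 ± 73.9 CPM, mm10 chromosome 9, 24097996 to 24316398, ENSMUSG00000043659.11) and Cntnap5a, an adhesion molecule (0 against 68.6 ± 34.9 CPM, at least 1013-fold lower in AD). The synaptic organiser Cbln1 (1.59 ± 0.761 against 346 ± 74.8 CPM) and the peptide cholecystokinin, Cck (63.4 ± 39.2 against 564 ± 206 CPM), were higher in AV too.

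Of 33 voltage-gated potassium channel genes, 2 were higher and 10 lower (3 and 11 over the list alone) in AD. Relative to the remaining genes the list lay lower in AD (camera adjusted p = 9.07e-05, and 0.00731 with an estimated correlation). Kcnq3 (52.6 ± 38.1 against 2171 ± 869 CPM) and Kcnip3 (0.1001 ± 0.149 against 33.0 ± 17.7 CPM) fell. Of 43 transcription factors, 3 were higher and 14 lower (3 and 18 over the list alone). The list as a whole lay lower in AD (camera adjusted p = 9.07e-05, and 0.00731 with an estimated correlation). Nr2f1 (3.80 ± 2.58 against 49.7 ± 13.7 CPM) and Mef2c (56.2 ± 39.2 against 286 ± 82.6 CPM) fell, and Bhlhe22 had no read in AV (11.3 ± 11.7 against 0 CPM, at least 387-fold). Among 56 adhesion genes, 6 were higher and 15 lower (8 and 20 over the list alone). Against all other genes the list lay lower in AD (camera adjusted p = 4.99e-05, and 0.00851 with an estimated correlation). Pcdh7 (0.209 ± 0.224 against 43.6 ± 12.9 CPM) and Adgrl2 (9.60 ± 4.52 against 289 ± 59.1 CPM) fell and Tenm4 rose (610.4 ± 129 against 184 ± 60.1 CPM). Of 14 neurofilament and axon caliber genes, 3 were higher and 2 lower (5 and 2 over the list alone). Set against other genes, these lay higher in AD (camera adjusted p = 0.00406, and 0.0468 with an estimated correlation). Nefl was 1 of the higher ones (1008 ± 360.5 against 447 ± 123 CPM). Of 37 vesicle and release genes, 12 were higher and 5 lower (16 and 8 over the list alone). Of 24 glutamate receptor genes, 2 were higher and 6 lower (6 and 10 over the list alone). Both lists lost their call when the correlation was estimated (camera adjusted p = 0.0398 for each, and 0.0968 with an estimated correlation). Astrocyte markers summed to 959 ± 166 CPM in AD against 1890.2 ± 290.4 in AV (1 of 3 called higher and 1 lower) and interferon and MHC class I genes to 240.2 ± 38.5 against 87.4 ± 37.8 (2 of 9 higher), and neither list was called (camera adjusted p = 0.805 and 0.0725). Within the 1 shared date (4 libraries against 5) the count was 792. DESeq2 called 1857 genes, 30.5% of them higher in AD against 49.0% with edgeR, and a fit of the 2 groups alone called 475.

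LD, labelled from the same retrosplenial cortex, differed from AV in 909 genes, with 592 higher in LD (n = 5) and 317 higher in AV (n = 8). LD was higher in Iqcj, which had no read in AV (25.3 ± 19.5 against 0 CPM, at least 870.0-fold), and the release factor Unc13c (54.0 ± 19.5 against 0.0679 ± 0.111 CPM, edgeR adjusted p = 5.17e-13). Slc17a7 (382 ± 235 against 8.11 ± 9.81 CPM) and Necab1 (369 ± 408 against 5.51 ± 7.52 CPM) were higher as well. AV was higher in the secreted C1q-like protein C1ql3 (0 against 93.4 ± 44.2 CPM, at least 1694-fold lower in LD). Among 56 adhesion genes, 17 were higher and 4 lower (24 and 11 over the list alone) in LD. Of 23 calcium-binding protein genes, 8 were higher and 1 lower (9 and 5 over the list alone). Of 20 calcium channel genes, 7 were higher and 0 lower (8 and 0 over the list alone). Of 24 glutamate receptor genes, 8 were higher and 2 lower (9 and 2 over the list alone). Each of these lists lay higher in LD (camera adjusted p = 4.80e-08, 2.64e-06, 0.000227 and 0.00831, and 0.00112, 0.00113, 0.00276 and 0.0319 with an estimated correlation). They are among 8 lists kept with an estimated correlation. Cortical and hippocampal excitatory markers summed to 359 ± 100 CPM in LD against 1228 ± 203 in AV. Astrocyte markers summed to 913 ± 378 against 1890 ± 290 and inhibitory neuron markers to 31.2 ± 32.1 against 8.74 ± 5.71. The count fell to 128 within the shared date (2 libraries against 3) and to 297 in a fit of the 2 groups alone. DESeq2 called 1746 genes, 41.2% of them higher in LD against 65.1% with edgeR.

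VA differed from VL in 365 genes, with 226 higher in VA (n = 8) and 139 higher in VL (n = 6). VA was higher in the peptide gene Calca (12.2 ± 9.46 against 0.0295 ± 0.0723 CPM, 414-fold (counting interval 148 to 2097)), the sulfotransferase Hs3st3a1 (14.4 ± 17.6 against 0.0276 ± 0.0304 CPM) and Tmie (37.3 ± 27.5 against 0.282 ± 0.447 CPM). Necab1 (1328 ± 304 against 100.5 ± 54.4 CPM, edgeR adjusted p = 9.22e-05) and Calb1 (542 ± 211 against 127 ± 68.7 CPM) were higher in VA too. VL was higher in the potassium channel subunit Kcne4 (0.0493 ± 0.0970 against 15.2 ± 10.6 CPM) and the phosphodiesterase Pde3a (0.133 ± 0.126 against 22.0 ± 22.4 CPM). Of 20 GABA and glycine receptor genes, 4 were higher and 0 lower (7 and 0 over the list alone) in VA. Against all other genes the list lay higher in VA (camera adjusted p = 0.000356, and 0.0172 with an estimated correlation). Among 56 adhesion genes, 6 were higher and 1 lower (15 and 1 over the list alone). Set against other genes, these lay higher in VA (camera adjusted p = 0.000130, and 0.0200 with an estimated correlation). Of 12 oligodendrocyte markers, 0 were higher and 0 lower (4 and 0 over the list alone). Camera placed the list higher in VA (camera adjusted p = 0.00476, and 0.284 with an estimated correlation). Their sum was 728.8 ± 1512 CPM in VA and 102.2 ± 87.2 in VL, with 4425 CPM in VA replicate 3. The count fell to 168 within the 2 shared dates (6 libraries each), to 211 without VA replicates 3 and 8 and VL replicate 4, and to 202 in a fit of the 2 groups alone. It rose to 820 with DESeq2 and 627 with the newer quasi-likelihood fit. By the recorded sex VA held 7 libraries from females and 1 from a male, and VL 2 and 3, but Xist went against the record of VA replicate 8 and VL replicate 4.

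RE differed from AM in 304 genes, with 101 higher in RE (n = 8) and 203 higher in AM (n = 4). RE was higher in Adamtsl1, a secreted matrix protein (26.9 ± 9.51 against 0.0150 ± 0.0300 CPM, 1795-fold (counting interval 354 to 77804)). AM was higher in the nuclear receptor Pparg, which had no read in RE (0 against 11.5 ± 14.6 CPM, at least 601-fold lower in RE), and the collagen Col27a1 (0.0426 ± 0.0556 against 53.7 ± 33.1 CPM, edgeR adjusted p = 3.34e-07). Cyyr1 (0.0538 ± 0.152 against 30.8 ± 11.8 CPM) and Slc17a6 (717 ± 115 against 1464 ± 249 CPM, edgeR adjusted p = 1.14e-05) were higher in AM too. The lists of potassium channels (camera adjusted p = 0.000645, and 0.0124 with an estimated correlation) and transcription factors (camera adjusted p = 2.29e-05, and 0.00260 with an estimated correlation) lay lower in RE. Of markers of other cells, inhibitory neuron markers summed to 89.6 ± 36.2 CPM in RE against 1.78 ± 2.59 in AM, astrocyte markers to 1286 ± 194 against 2990.0 ± 326 and cortical and hippocampal excitatory markers to 82.4 ± 45.3 against 686 ± 89.5. Only the last list was called (camera adjusted p = 3.53e-06, and 4.32e-05 with an estimated correlation). All 4 AM libraries came from animals that also gave an RE library of the same number. With the animal as a block these 4 pairs called 202 genes, the replicate block in the fit of all libraries called 282, and without AM replicate 3 the count was 187. DESeq2 called 544 genes, 56.3% of them higher in RE against 33.2% with edgeR, the newer quasi-likelihood fit called 617, limma-voom 600 and a fit of the 2 groups alone 614. Within the 1 shared date (4 libraries each) the count was 219. RE held 5 libraries from females and 3 from males and AM 4 from females.

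No gene was called between IAD (n = 3) and AM (n = 4) by edgeR's quasi-likelihood test, with 504 at an unadjusted p under 0.05. DESeq2 called 240 genes and the newer quasi-likelihood fit 5. Among the genes fixed beforehand, Slc17a6 stood at 1572 ± 63.6 against 1464 ± 249 CPM, Tcf7l2 at 1728 ± 204 against 1983 ± 391 CPM and Calb1 at 204 ± 25.6 against 215 ± 81.6 CPM. The 2 groups share no amplification date.

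PF differed from the mean of CL, PCN and CM, the other intralaminar nuclei labelled from the striatum by AAV, in 10 genes, 8 of them higher in PF (n = 4 against 12). Sparcl1, a matricellular protein, was lower in PF (46.2 ± 19.0 against 371 ± 176 CPM, edgeR adjusted p = 6.20e-11), as was the protocadherin Pcdh10 (135 ± 43.6 against 369 ± 123 CPM), a call lost without PF replicate 2. Higher in PF were Nrg1, the growth factor neuregulin 1 (18.6 ± 5.08 against 3.57 ± 6.47 CPM), the calcium release channel Ryr2 (7.08 ± 6.06 against 0.199 ± 0.441 CPM), Cdh22 (2.10 ± 1.48 against 0 CPM) and Chrm1 (1.98 ± 3.5002 against 0 CPM). Each of these lost its call under at least 1 other setting. Of 43 transcription factors and 16 immediate early genes none was called, while both lists lay lower in PF (camera adjusted p = 0.00152 and 0.000457, and 0.0198 for both with an estimated correlation). Camera called 6 of 23 lists, 5 also with an estimated correlation, while another list test, fry, called 0. All 16 libraries share 1 amplification date. Leaving out PF replicate 2, PCN replicate 2, PCN replicate 3 or CM replicate 1 each lowered the count to 6. DESeq2 called 274 genes, 68.6% of them higher in PF against 80% with edgeR, the newer quasi-likelihood fit 24, limma-voom 23 and a fit of the 4 groups alone 5.

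PVT differed from the same 3 intralaminar nuclei in 360 genes, with 200 higher in PVT (n = 3) and 160 lower. PVT was higher in Calb2 (745 ± 190.3 against 83.1 ± 69.1 CPM, edgeR adjusted p = 0.00228) and peripherin, the intermediate filament Prph (101 ± 27.9 against 3.89 ± 9.74 CPM, edgeR adjusted p = 0.000582). Vwa5b1 (27.3 ± 19.9 against 1.32 ± 2.26 CPM) and the chromatin protein Hmgn5 (11.5 ± 9.63 against 0.172 ± 0.254 CPM) were higher too. It was lower in the RNA-editing family member Adarb2 (0.414 ± 0.426 against 27.5 ± 13.6 CPM, edgeR adjusted p = 3.13e-08) and in Mrvi1 (1.519 ± 1.78 against 27.9 ± 15.1 CPM). No list kept a call with an estimated correlation. The nearest, transcription factors, lay lower in PVT, with 0 higher and 4 lower (1 and 10 over the list alone, camera adjusted p = 0.00705, and 0.0610 with an estimated correlation). Habenula markers summed to 43.1 ± 10.1 CPM in PVT against 13.5 ± 6.44, 8.81 ± 6.08 and 20.6 ± 5.67 in CL, PCN and CM. Astrocyte markers summed to 1889 ± 154 against 2578 ± 77.6, 2707 ± 208 and 2216 ± 97.0. The 3 PVT libraries came from females and share no amplification date with the 12 others. The RNA Rn18s held 0.338 to 0.658% of their counts against 2.87 to 4.74%, and PCN and CM carried tdTom in place of GFP. The count was 198 without PVT replicate 1 and 156 without replicate 2. DESeq2 called 1152 genes, 26.2% of them higher in PVT against 55.6% with edgeR, the newer quasi-likelihood fit 1083, limma-voom 935 and a fit of the 4 groups alone 1031.

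CM neurons labelled from the striatum by DiI (n = 3) and by AAV (n = 4) differed in 1 gene, Crebzf, a bZIP transcription factor, at 347 ± 520.3 against 51.0 ± 16.01 CPM for DiI and AAV (edgeR adjusted p = 0.00447). At an unadjusted p under 0.05 there were 1073 genes. Without DiI replicate 2 the Crebzf difference turned to -0.118 on the log2 scale and the call was lost, as it was without AAV replicate 3 or 4. DESeq2 called 474 genes, 48.3% of them higher with DiI against 100% with edgeR, the newer quasi-likelihood fit 9, limma-voom 26 and a fit of the 2 groups alone 12. Of 23 lists camera called 4, of which the 2 habenula markers, lower with DiI, kept the call (sums of 3.47 ± 0.705 against 20.6 ± 5.67 CPM, camera adjusted p = 0.00519, and 0.0149 with an estimated correlation). The tracers share no amplification date, and Rn18s held 0.725 to 1.30% of counts with DiI against 3.29 to 4.26%.

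Each nucleus was also set against the mean of the other 21, which called between 486 genes higher in IAD and 3908 in MD. In 10 nuclei the gene picked by the rule for markers had every library above all libraries of other nuclei. AD was marked by C1ql2, a secreted C1q-like protein, at 256 ± 83.5 CPM (n = 4) against 1.36 ± 3.15 (n = 8) in AV. AV was marked by Npsr1 at 189 ± 73.9 CPM (n = 8) against 24.9 ± 18.1 (n = 6) in VL. RE was marked by the organic anion transporter Slco1a5 (23.4 ± 28.9 CPM (n = 8) against 0.284 ± 0.695 (n = 6) in VM). LGd was marked by Scnn1a (40.1 ± 8.64 CPM (n = 5) against 6.52 ± 5.18 (n = 4) in VB) and VB by the prostaglandin transporter Slco2a1 (164 ± 40.9 CPM (n = 4) against 79.2 ± 22.2 (n = 5) in LGd). VPMpc was marked by the zinc finger protein Bnc2 (207 ± 80.9 CPM (n = 6) against 9.97 ± 12.5 (n = 8) in RE). LD was marked by the complement regulator Cd59a (182 ± 57.8 CPM (n = 5) against 43.2 ± 20.9 (n = 8) in VA) and SPA by Gprin3 (249.8 ± 63.8 CPM (n = 4) against 133 ± 16.4 (n = 4) in IMD). Midline nuclei were marked by the collagen Col12a1 in PVT (636 ± 51.7 CPM (n = 3) against 389.9 ± 139.9 (n = 4) in IMD) and the growth factor Fgf16 in IMD (21.9 ± 2.39 CPM (n = 4) against 6.92 ± 2.84 (n = 3) in PVT). In VA the top gene was Sox10, a transcription factor of the oligodendrocyte lineage (11.1 ± 16.2 CPM (n = 8) against 0.911 ± 1.04 (n = 4) in VB), and its libraries spanned 0 to 36.1 CPM. DESeq2 called 21149 genes higher over all 22 nuclei, against 33985 with edgeR, and no longer called C1ql2 in AD or Slco1a5 in RE.

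**Figure D4:**
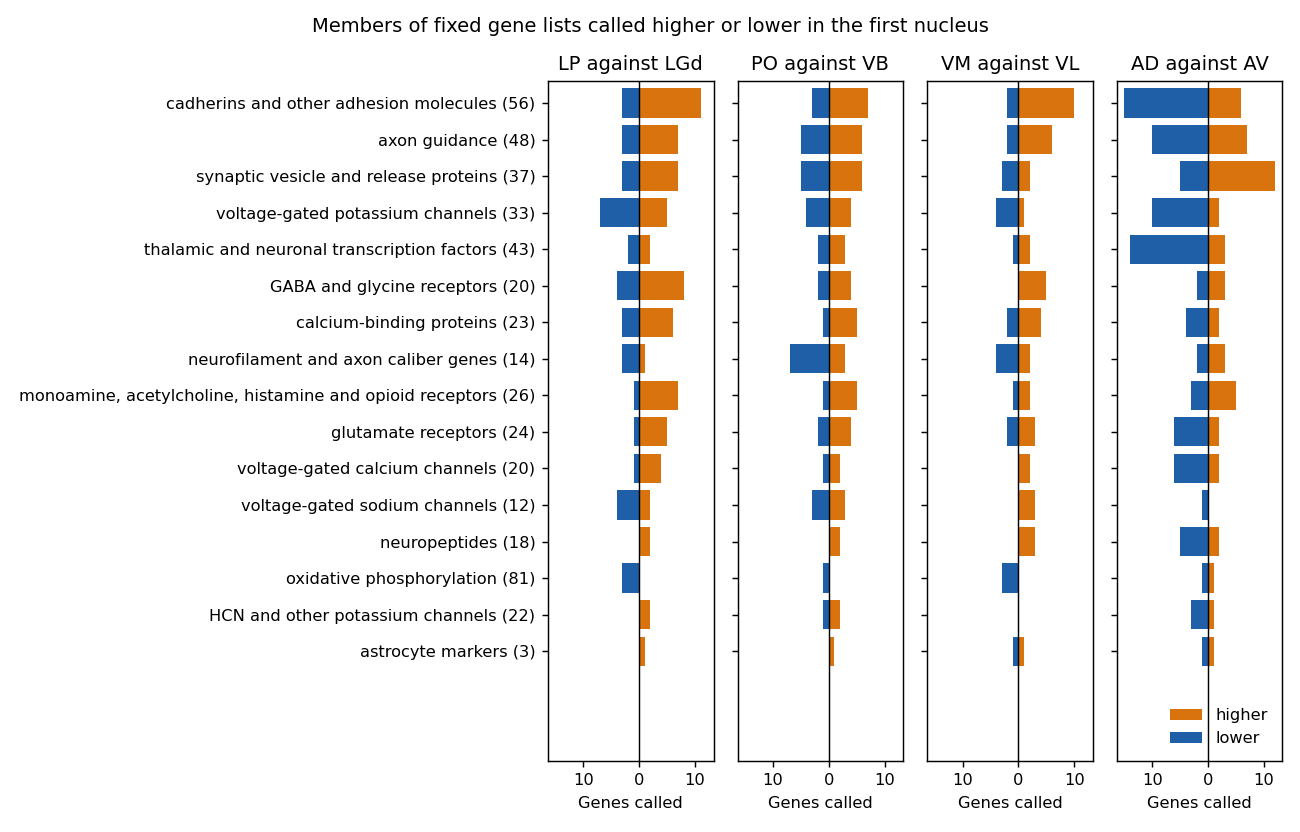
Number of genes called per gene list in LP against LGd, PO against VB, VM against VL and AD against AV. Orange bars to the right count genes higher in the nucleus named first and blue bars to the left genes lower in it, and the number of measured members stands in parentheses after each list. Of 56 adhesion genes 11, 7, 10 and 6 were higher and 3, 3, 2 and 15 lower in the 4 comparisons.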

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

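The tests here were chosen after the results were seen, except that of sex on principal component 1. Igkc stood at a mean of 33.8 CPM in the 30 striatum-labelled libraries. The AAV tracer is argued against, since the lowest CM library labelled by DiI had 8.30 CPM and the highest cortex-labelled library 0.0539, and the AM library labelled by AAV had 0. Amplification date is argued against by the 2 dates that hold both classes, with a lowest striatum-labelled value of 8.30 against a highest cortex-labelled value of 0.0517 CPM. RNA from B cells is argued against, as Cd74 and Ighm, abundant in B cells, summed to a mean of 0.208 CPM (SE 0.126) in the striatum-labelled libraries and 1.72 in the others. Coro1a (31.002 against 28.0149 CPM), high without Igkc, was left out of the sum afterwards. Plasma cells, which may carry little of both, were not tested. Whether Igkc may follow the nucleus or the injection in the striatum cannot be told apart, since 0 nuclei were labelled from both targets, and reads of another transcript of the locus were not tested.

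Principal component 1 parted the 7 striatum-labelled nuclei from the 15 others, with class means 53.99 apart. Against the AAV tracer as the whole cause, CM libraries labelled by DiI scored at most -22.97, below the lowest cortex-labelled nucleus at -14.59. With nuclei labelled by DiI alone, component 1 (31.8% of the variance) ordered the 15 cortex-labelled nuclei much as before (rho = 0.914), but CM (-21.6) did not part from them (lowest -38.9), so a share of the tracer in the axis stays open. Sex is argued against, as females differed from males by -1.43 within 7 groups (SE 2.02, permutation p = 0.374 from 20000 permutations), and so is amplification date, as the gaps within the 2 dates that hold both classes were 33.8 and 57.9. A candidate explanation is that projection class or nuclear group shapes the transcriptome, a hypothesis found and examined on the same data, and the target was not varied within a nucleus.

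The number of genes called higher in a nucleus than in the other 21 may follow the libraries as much as the nucleus. Over 22 nuclei it fell with the mean number of genes detected (Spearman rho = -0.659, permutation adjusted p = 0.00202 over 4 relations; Pearson r = -0.711, or -0.604 without MD and SPA). It rose with the number of libraries (rho = 0.730, adjusted p = 0.00084; r = 0.644, or 0.654 without LP and VA). It also fell with the mean correlation of a library with its group (rho = -0.637, adjusted p = 0.00252; r = -0.779, or -0.491 without MD and VPMpc). The first 2 explanations had the values they need, and a difference between the nuclei themselves stays open.

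Libraries were also regrouped at random. Chance was excluded for the 22 nuclei (9113 genes against 2952 in the highest other split, 1 of 100 splits as large), LP against LGd (599 and 245, 1 of 100), PO against VB (438 and 85, 1 of 100) and VM against VL (280 and 78, 1 of 100). It was excluded too for AD (940 and 332), VA (365 and 106) and LD (909 and 672), each with 1 of 100, for PVT (360 and 42, 1 of 40) and for striatum-labelled against cortex-labelled nuclei (2837 and 1, 1 of 100). For each nucleus against the others, genes called higher were summed over the 22 nuclei on a sample of 500 genes. The real split gave 1038 such calls and the highest of 49 others 458 (median 404, 1 of 50). This sum does not exclude chance for any single nucleus. For RE against AM the real split called 304 genes and the highest other 56 (1 of 100). Of its other splits, 3 parted all 4 pairs of libraries from an animal, as the real one does, and called at most 2. Chance was not excluded for PF (10 genes, highest other 21, 11 of 40 splits), the 2 tracers in CM (1 and 2, 19 of 35) or IAD against AM (0 and 1, 35 of 35).

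Samples far from the others of their group made up 69 of 395 tests by Dixon's gap ratio, which chance gives in about 1 in 20 groups. Each is given as its CPM, or its component 1 score, with the range of the others. In AM labelled by DiI these were Adamtsl1 (0.0600, others 0) in replicate 2, and Calb1 (337, 163 to 181) and Pparg (33.4, 3.19 to 5.58) in replicate 3. In VM these were Cox6a2 (8.24, 0 to 0.934) in replicate 1, Adgrg6 (34.5, 9.95 to 18.7) and Slco1a5 (1.70, others 0) in replicate 5, and Dio2 (0.793, 0 to 0.296) in replicate 6. In VL these were Calca (0.177, others 0) and Pcdh9 (714, 999 to 1152) in replicate 1, and Cdh8 (85.6, 34.8 to 47.4), Ntrk3 (3.59, 0.0678 to 0.708), Pde3a (63.7, 1.83 to 24.6) and the oligodendrocyte sum (277, 42.3 to 87.4) in replicate 2. VL also had Adgrg6 (0.0678, others 0), Dio2 (119.5, 11.9 to 29.6) and Glra3 (0.407, 0 to 0.0590) in replicate 3, and Tmie (1.19, 0.0499 to 0.150) in replicate 4. In AD these were the oligodendrocyte sum (146, 21.8 to 25.7) in replicate 1, and Calb1 (5.31, 0 to 0.157) and Gpr139 (158, 259 to 273) in replicate 2. AD also had Adgrl2 (16.3, 6.34 to 7.88) in replicate 3, and Npsr1 (0.0829, others 0) in replicate 4. In LGd these were Calb2 (20.96, 0.243 to 4.88), Grin3a (10.8, 0.581 to 2.42) and Plxnc1 (136, 41.5 to 58.2) in replicate 1, and Cacna1e (25.95, 0 to 1.28), Htr2c (7.12, 0 to 1.27) and the component 1 score (41.7, 44.7 to 45.8) in replicate 2. LGd also had Atp2b4 (0.162, others 0) and the oligodendrocyte sum (275, 20.9 to 84.4) in replicate 3, and Cbln4 (2.31, 0 to 0.56782), Nxph1 (1.27, 0.162 to 0.465) and Robo2 (28.4, 9.54 to 13.9) in replicate 4. In RE these were Slco1a5 (93.6, 5.73 to 24.8) in replicate 3, and Cyyr1 (0.430, others 0) in replicate 5. RE also had Bnc2 (38.4, 0.311 to 13.4) in replicate 6, and the oligodendrocyte sum (398, 18.5 to 90.1) in replicate 8. In AV these were Chrm1 (0.248, others 0), Gabra2 (72.4, 1.87 to 5.90) and S100a10 (0.124, others 0) in replicate 1, Grin2b (5409, 3024 to 4110.1) and Necab1 (22.5, 0 to 7.57) in replicate 3, and C1ql2 (9.12, 0 to 0.992) in replicate 4. In PF these were Chrm1 (7.21, 0 to 0.714) in replicate 2. In PO these were Grin3a (172, 102 to 128) in replicate 1, and Lrrtm4 (119.5, 21.9 to 63.2) in replicate 4. PO also had Fam19a1 (0.0743, others 0) in replicate 5, and the oligodendrocyte sum (322, 37.4 to 139) in replicate 6. In VB these were Grin3a (45.6, 0.102 to 2.20) in replicate 1, Foxp2 (238, 56.7 to 78.8), Gcnt4 (11.2, 39.4 to 44), Rorb (2422, 913 to 1137) and Slc24a2 (9728, 4929.5 to 5711) in replicate 2, and Syt16 (5.33, 0.204 to 0.791) in replicate 4. In CM labelled by AAV these were Ryr2 (1.502, others 0) in replicate 3, and Hmgn5 (0.392, others 0) and Vwa5b1 (5.68, others 0) in replicate 4. In VA these were Hs3st3a1 (53.5, 0.131 to 22.1) in replicate 1, and the oligodendrocyte sum (4425, 19.7 to 751) in replicate 3. In CL these were Mrvi1 (19.8, 9.13 to 10.03) in replicate 2, and Ryr2 (0.56804, 0.0551 to 0.141) in replicate 4. In LP these were the oligodendrocyte sum (1102, 31.3 to 474) in replicate 1, and Pvalb (0.620, 0 to 0.128) and the component 1 score (25.96, 11.01 to 17.98) in replicate 2. LP also had Pcdh17 (267, 43.8 to 139.9) in replicate 6, and Scnn1a (0.206, others 0) in replicate 8. In PCN these were Prph (1.49, 0 to 0.0613) and Ryr2 (0.0496, others 0) in replicate 3. In LD these were the oligodendrocyte sum (184, 24.8 to 57.9) in replicate 2.

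The changes of the 3 comparisons LP against LGd, PO against VB and VM against VL were tested for differences with an interaction contrast in edgeR. LP and PO differed in 33 genes, LP and VM in 123 and PO and VM in 56. Called in opposite directions were Srgap3 and Sorl1 between LP and PO, with log2 changes 2.82 and 6.25 apart. Among 7 such genes between LP and VM were Col25a1 (-4.95), Pde3a (14.26), Nmbr (18.19), Hs3st3a1 (-12.82), Erich5 (11.90) and Sorcs3 (-3.94). The 4 between PO and VM were Col25a1 (-4.31), Drd5 (16.78), Parm1 (-15.62) and Pde3a (14.68). The VM calls of Drd5, Pde3a and Hs3st3a1 were lost within the shared date, that of Drd5 also with the newer quasi-likelihood fit and limma-voom. Differences above 10 involve groups at or near 0 and depend on the prior count.

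Xist, set against the recorded sex, stood at 1183 CPM in VM replicate 4, 744.6 in VL replicate 4 and 1204 in VA replicate 8, which are recorded as male. The 69 other libraries recorded as male had at most 6.36 CPM. VL replicate 3, recorded as a mix of both sexes, had 1005 CPM of Xist and 0.678 CPM over the Y-linked genes.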

How the results depend on the processing

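Chosen after the results were seen were the settings so named above (within dates for striatum against cortex too) and the components without Xist, Tsix and Y-linked genes. Apart from left-out libraries, 103 of 151 settings of counts and shares stayed within 1.5 times the count, or within the spread, and 48 did not, where any change in the share of component 1 is included. The cause was not tested for these, except that fits within dates, of animals that gave both sides and without libraries hold fewer samples. DESeq2 called 1146 genes for LP, 1214 for PO, 681 for VM, 1857 for AD, 274 for PF, 820 for VA, 1746 for LD, 544 for RE, 240 for IAD, 1152 for PVT, 474 for CM and 21149 for each nucleus against the others. The newer quasi-likelihood fit called 522 for VM, 24 for PF, 627 for VA, 617 for RE, 5 for IAD, 1083 for PVT and 9 for CM. Limma-voom called 492 for VM, 23 for PF, 600 for RE, 935 for PVT and 26 for CM. A fit of the compared groups alone called 475 for AD, 5 for PF, 202 for VA, 297 for LD, 614 for RE, 1031 for PVT and 12 for CM. Within shared dates the counts were 205 for PO, 163 for VM, 168 for VA, 128 for LD and 874 for striatum against cortex, where the log2 differences of Stmn3 (-0.379) and Ndufa2 (-0.0506) turned, and without doubted libraries 158 for VM and 211 for VA. Animals that gave both sides, with the animal as a block, gave 115 for VM (125 without the block) and 202 for RE. The share of variance on component 1 was 49.8% without doubted libraries, 47.3% with 1000 genes, 48.7% with genes picked by variance, 49.997% with RLE values, 31.8% with nuclei labelled by DiI alone and 49.7% without the sex genes. With the correlation estimated, 39 gene list tests were called, against 78 with the preset correlation. RLE moved no median of all genes by over 0.1 on the log2 scale.

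Without single libraries, the counts ran from 6 to 12 for PF, 187 to 292 for RE, 0 to 1 for IAD, 156 to 325 for PVT and 0 to 2 for CM. Of these, PF fell to 6 without PF replicate 2, PCN replicate 2 or 3 or CM replicate 1, RE to 187 without AM replicate 3, and PVT to 198 and 156 without PVT replicates 1 and 2. IAD rose to 1 without AM replicate 1, 2 or 4, and CM fell to 0 without AAV replicate 3 or 4 or DiI replicate 2 and rose to 2 without DiI replicate 1. The counts for the other comparisons stayed within 1.5 times, namely 467 to 622 for LP, 308 to 410 for PO, 187 to 283 for VM, 705 to 923 for AD, 266 to 354 for VA and 648 to 951 for LD. In CM the log2 difference of Crebzf ran from -0.118 without DiI replicate 2, where it turned, to 3.31. Of 414 calls of named genes 266 were kept in every setting, 133 were lost in at least 1 other setting and 65 without a single library.

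For RE and AM the replicate numbers pair the libraries. The replicate block gave 282 calls there, within 1.5 times the count without it, and changed no call of their named genes. It spanned all groups, so only the animal block above models this pairing. Elsewhere the numbers do not pair the libraries, although for VM, AD and VA some came from the same animal. There the replicate block gave 522 for LP, 433 for PO, 259 for VM, 836 for AD, 9 for PF, 290 for VA, 757 for LD, 0 for IAD, 288 for PVT, 1 for CM, 8280 for the 22 nuclei and 24530 for each nucleus against the others. Among single nuclei it moved the number of genes called higher by over 1.5 times in VA (1795 to 1020), VM (1106 to 653), AV (2613 to 1639), LP (2425 to 1219) and PO (1930 to 1180). No paired analysis was possible for striatum against cortex or the components, which rest on nuclei, or for the agreement between comparisons, which are not paired. In the simulations neither depth nor the number of libraries was varied on its own.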

Other observations

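The gene lists and the hypothesis on a shared axis were fixed before their results were seen, the relation in the last paragraph afterwards. Of 48 axon guidance genes 8 were higher and 7 lower in the striatum-labelled nuclei (10 and 8 adjusted over the list alone). Lower were Sema6a, a transmembrane semaphorin (35.7 ± 20.01 against 376 ± 152 CPM over nuclei, edgeR adjusted p = 1.60e-05), and the semaphorin receptor Nrp1 (0.823 ± 0.717 against 14.66 ± 13.8 CPM). Higher were the semaphorin Sema5b (76.7 ± 30.6 against 4.34 ± 7.13 CPM) and the ephrin receptor Ephb3 (16.9 ± 5.96 against 1.57 ± 1.74 CPM). The list did not stand apart from other genes (camera adjusted p = 0.297, and 0.566 with an estimated correlation). Within the shared dates, a setting chosen afterwards, Sema5b and Ephb3 lost their calls, and the other genes of this paragraph kept theirs in every setting run.

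The 2 measured habenula markers were higher in the striatum-labelled nuclei, Gpr151 at 16.8 ± 7.22 against 3.08 ± 2.99 CPM and Wif1 at 8.54 ± 6.52 against 0.339 ± 0.676 CPM (camera adjusted p = 0.0128, and 0.116 with an estimated correlation). Wif1 lost its call within the shared dates. In CM they summed to 3.47 CPM with DiI and 20.6 with AAV, so tracer or date stays open.

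A hypothesis was that the changes of LP against LGd, PO against VB and VM against VL run along the axis from cortex-labelled to striatum-labelled nuclei. Across genes, the correlation of each change with that axis, drawn without the 6 nuclei, was 0.0875 for LP (exact p = 0.342), 0.0919 for PO (p = 0.379) and -0.0270 for VM (p = 0.781), so the result was negative.

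The number of genes called higher per nucleus also fell with the mean total count (rho = -0.443, permutation adjusted p = 0.0399, or rho = -0.337 and unadjusted p = 0.146 without MD and AD).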
